A study of Apis mellifera with 12 samples.

How the data were processed

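Small RNA from honey bee (Apis mellifera) worker brains was profiled on 12 microarrays, 1 per pool. Per the labels, newly emerged workers received an abdominal injection of 2 µL of double-stranded RNA (dsRNA) at 10 µg/µL, directed either at vitellogenin (dsVg, the knockdown) or at green fluorescent protein (dsGFP, the sham control), and the workers were 15 days old when sampled. Brains were dissected singly, and RNA shorter than 200 nucleotides was separated from longer RNA. Each pool held 1 µg of that fraction, 200 ng from each of 5 bees, and there were 6 pools per treatment. If the pools hold different bees, the spread between pools includes both bee-to-bee and array-to-array differences.

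The authors deposited 1 scanner table per array and 1 table of processed values. Per the labels' protocols, a service provider added a poly(A) tail and an oligonucleotide tag to the RNA and stained it with Cy3, so each array has 1 colour. Per the file headers, each scanner table gives a spot's intensity on a linear scale and the spread of its pixels. The intensities still contain the background, because the 608 empty spots lie far above 0 (medians of 74.8 to 478 per array). An array holds 3968 spots, among them 168 honey bee miRNA probes with 18 spots each, synthetic calibration probes and 6 probes named for 5S RNA. The scanner, the image software and the miRNA annotation release are not given in the sources used here. The file header of dsGFP pool 1 calls its intensity a median where the headers of the other 11 arrays call it a mean, and all intensities of dsVg pool 5 are whole numbers (100% of spots, against at most 1.11% on the other arrays).

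The authors' table of processed values also holds intensity on a linear scale, as whole numbers, and its normalization method is not given in the sources used here. Its column medians ran from 22 to 29.5. Over the 33 miRNAs detected on all 12 arrays, each column followed the log2 values computed here from the same array before normalization. The r was 0.981 to 0.998 across these miRNAs, which are not independent replicates. Dimmer miRNAs were not compared in this way. After each of these miRNAs was centred, 11 of 12 columns correlated best with the normalized values of their own array. The exception was dsGFP pool 4, at 0.18 with its own array and 0.37 with another.

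Scanner intensities were corrected with normexp (offset 50, fitted on all spots) in limma 3.58.1 under R 4.3.3, the log2 values of the 18 spots of a probe were averaged, and the 168 miRNA probes were quantile-normalized between arrays. A miRNA counted as detected on an array when its mean intensity exceeded the 95th percentile of that array's empty spots, since the tables hold no background column. It was tested when detected on at least 6 of the 12 arrays, which left 84 miRNAs, 33 of them detected on all 12. Control probes were not tested. Empty spots behave differently from dim miRNA spots on part of the arrays: on 6 arrays (dsGFP pools 1, 3 and 4, dsVg pools 1, 2 and 3) most dim miRNA spots were brighter than the empty spots, and 97 to 168 miRNAs counted as detected, whereas on the other 6 they were level with or below the empty spots, and 34 to 60 did. The kinds were set by this count, above 80 or not. In dsGFP pools 5 and 6, of the second kind, the median miRNA intensity was slightly above that of the empty spots (291 against 276, 223 against 213). Each kind of array holds 3 pools of each group. Several miRNAs near background therefore entered the test only through the first kind, and their differences understate any change in abundance. Precision is limited by the number of arrays.

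The groups were compared with limma (lmFit and eBayes, two-sided) and Benjamini-Hochberg adjustment over the 84 miRNAs, with the knockdown minus the control as the direction. Every miRNA named also received a two-sided exact permutation test over the 924 assignments of 12 pools to 2 groups of 6, whose smallest possible p is 0.0021645. The number of detected miRNAs and the median signal per array were compared with the same exact test. Fixed lists of miRNAs (14 in all) were tested with limma's camera (preset correlation 0.01) where at least 3 members were tested. The same lists were run with an estimated correlation and with fry. Lists overlap, so their results are not independent. The grouping, the tests, the lists, the main alternative settings and the rule for naming miRNAs were chosen before the data were examined. The rule took all miRNAs past the adjusted threshold of 0.05, then the smallest unadjusted p-values until 20 were reached, up to 4 tested members of each list with the smallest p, and the 10 miRNAs with the highest mean signal, which gave 43 names.

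None of the 30 pairs of pools within a group agreed within spot noise (chi-square per degree of freedom of 35.6 to 1585), as copies of 1 array would. This does not exclude repeat hybridizations of 1 RNA, so the count of separate pools rests on the labels. The alternatives covered background correction, normalization between arrays, the filter on dim probes, the summary of spots, the variance model, array weights, the deposited table, the pool number as a block and leaving out each pool in turn. The files give no slide or scan, so a slide block was not run. The comparison was tested on simulated data with each miRNA's mean and within-group SD and independent normal noise, which leaves out array effects that miRNAs share. With 20 of 84 miRNAs changed, 45.5% of changes of 1.41-fold, 82.8% of 2-fold changes and 97.8% of 4-fold changes were recovered at an adjusted p under 0.05. The changes were added to processed log2 values, which leaves out their compression by the offset and by quantile normalization. Smaller numbers of changed miRNAs were not simulated. These shares therefore do not tell which changes in abundance would have been found. In a second simulation, a log2 change of -2 planted in 6 bright miRNAs came back as -1.95 without normalization and as -1.28 after quantile normalization, so large changes in bright miRNAs are compressed. No coordinates are printed, because the files name no genome build. The annotation table of assembly Amel_HAv3.1 was used only to find which miRNA genes neighbour each other, and 80 of the 84 tested miRNAs matched exactly 1 gene in it.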

Results

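The series measured miRNAs in the brains of 15-day-old honey bee workers after RNA interference against vitellogenin, the yolk precursor protein that in workers is tied to hormone signalling and the pace of behavioural maturation. The question was whether lowering vitellogenin changed the brain's miRNA population. Control bees received dsRNA against green fluorescent protein, which bees lack. There were 6 pools of 5 brains per treatment, each on its own array. The source names call the samples forager brains while the labels give an age of 15 days, and behaviour was not used as a factor. Vitellogenin mRNA was not among the molecules measured on these arrays, so the extent of the knockdown was not analysed here. Of 168 miRNA probes, 84 were tested, and 33 were detected on all 12 arrays. The probes with the highest mean signal were miR-252, miR-184, miR-87, miR-317, miR-276, miR-2796, miR-277, miR-34, miR-2 and miR-13b. Probes differ in how well they bind, so this order describes signal and not abundance.

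Array-wide signal was compared first, because normalization removes any shift that all miRNAs share. The number of detected miRNAs was 97.3 ± 48.7 (SD, n = 6 pools) in controls and 86.3 ± 51.7 (SD, n = 6 pools) after knockdown, a difference of -11 (two-sided exact permutation p = 0.701). The median log2 signal over all 168 probes before normalization was 6.62 ± 0.30 in controls and 6.68 ± 0.40 after knockdown, a difference of 0.06 (exact permutation p = 0.790). Both differences were smaller than the spread between pools, and the sign of each rests on single pools. The difference in detected miRNAs became 2.53 without dsGFP pool 1 and 8.33 with a threshold of 3 background SDs. The difference in signal became -0.022 without dsGFP pool 3, -0.037 without dsVg pool 1 and -0.047 without dsVg pool 5. The median probe lay near the empty spots (raw intensity 113 against 147 in dsVg pool 4, 223 against 213 in dsGFP pool 6). The median therefore cannot show a shift of the bright miRNAs alone. The difference was 0.19 at the 75th percentile of the probes (exact permutation p = 0.610) and 0.11 for the median of all spots (exact permutation p = 0.641). Within the arrays whose dim spots lay above the empty spots the differences were -11.3 miRNAs and 0.15 in log2 signal, and within the others -10.7 and -0.034. The 2 kinds of array were set by the number of detected miRNAs itself, so the differences in that number within them decide nothing.

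In the knockdown brains, the miRNAs that stood farthest from controls relative to their error were miR-375, miR-1 and miR-275. The signal of miR-375, a miRNA of endocrine cells in vertebrates, was 7.26 ± 0.23 in controls and 6.88 ± 0.16 after knockdown (log2, SD, n = 6), a difference of -0.38 (SE 0.12), with all 6 knockdown pools below the control mean. For miR-1, a conserved muscle miRNA, the levels were 8.96 ± 0.63 and 8.06 ± 0.74, a difference of -0.90 (SE 0.37), again with 6 of 6 knockdown pools below the control mean. For miR-275, which acts in the mosquito gut and fat body after a blood meal, they were 9.97 ± 0.28 and 10.58 ± 0.64, a difference of 0.61 (SE 0.27), with 5 of 6 knockdown pools above the control mean. None of these differences passed adjustment for 84 tests. Their size followed the processing. It was -1.63 for miR-375 with plain background subtraction, -0.61 under scaling to the 75th percentile, -0.58 in the deposited table, -0.21 under scaling to the median and -0.15 without normalization. For miR-1 it was -1.76 with plain subtraction, -0.56 under scaling to the median and -0.50 without normalization. For miR-275 it was 0.095 under scaling to the 75th percentile, 0.28 with cyclic loess, 0.38 without dsVg pool 5 and 0.28 without dsVg pools 1 and 5.

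With limma, 0 of 84 miRNAs had an adjusted p under 0.05, and 0 had one under 0.1. The smallest adjusted p was 0.622, that of miR-375 (unadjusted limma p = 0.00741, exact permutation p = 0.0130). At an unadjusted p under 0.05 there were 3 miRNAs, 1 higher and 2 lower after knockdown, where 4.2 are expected by chance, and the exact permutation test also gave 3. For miR-1 the unadjusted limma p was 0.0306 (exact permutation p = 0.0368), and for miR-275 it was 0.0425 (exact permutation p = 0.0368), both with an adjusted p of 0.666. The count of 3 depends on single pools: it was 13 without dsVg pool 3, 8 without dsVg pool 6, and 1 without dsGFP pool 1, dsGFP pool 5 or dsVg pool 1. With arrays weighted by their quality, 1 miRNA passed the adjusted threshold, miR-375 (-0.44, adjusted p = 0.0385 with limma, 0.0385 to 0.984 over its 34 alternatives). Within the arrays whose dim spots lay above the empty spots, the differences of miR-375, miR-1 and miR-275 were -0.17, -1.17 and 0.34, and within the other arrays they were -0.59, -0.64 and 0.88. The signal of miR-375 was above the empty spots on all 6 control arrays and on 3 of 6 knockdown arrays.

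**Figure D1:**
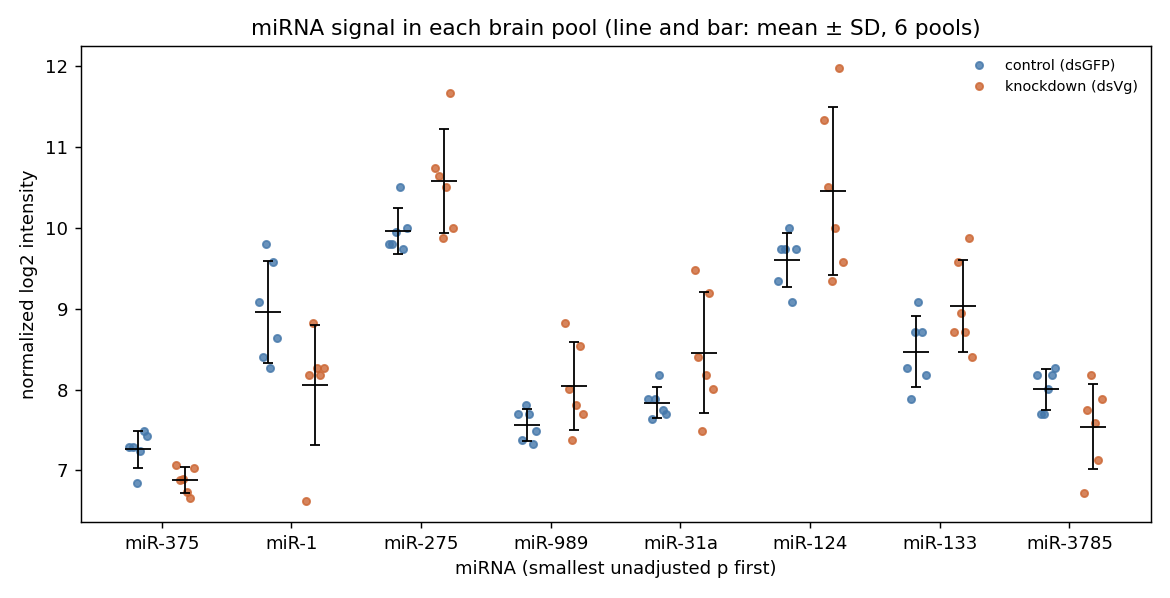
Normalized log2 intensity (vertical axis) of the 8 miRNAs with the smallest unadjusted p, each point 1 pool of 5 brains, with the mean as a line and the SD as a bar (n = 6 pools per group). The knockdown pools of miR-375 and miR-1 all lie below the control mean, while those of miR-124 spread more widely than its controls (10.46 ± 1.04 against 9.60 ± 0.33).

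Next in order of p-value came miR-989 (0.48, SE 0.22), miR-31a (0.62, SE 0.30), the neuronal miRNA miR-124 (0.85, SE 0.41), miR-133 (0.57, SE 0.27), miR-3785 (-0.46, SE 0.23), miR-92a (0.33, SE 0.17) and miR-3049 (0.51, SE 0.26), with unadjusted limma p-values of 0.0547 to 0.0792. For miR-124 the signal was 9.60 ± 0.33 in controls and 10.46 ± 1.04 after knockdown, and 4 of 6 knockdown pools lay above the control mean. Most of these differences depend on the scaling or on single pools. Scaling to the 75th percentile moves all differences by the same amount from those without normalization, so its effects are not separate for each miRNA. Scaling to the 75th percentile gave miR-989 -0.030, miR-92a -0.17, miR-3049 -0.0061, miR-31a 0.082, miR-133 0.11 and miR-124 0.28, and miR-3785 was at -0.15 under scaling to the median and -0.093 without normalization. The difference of miR-124 was 0.55 without dsVg pool 5 and 0.25 without dsVg pools 1 and 5. The differences of miR-305 (-0.29), miR-3789 (-0.83), miR-92b (0.15), miR-12 (-0.28), miR-13b (-0.48), miR-279c (0.51), miR-971 (0.49), miR-3719 (0.51), miR-71 (-0.38) and miR-306 (-0.10) had unadjusted limma p-values of 0.117 to 0.234. None of these passed the adjusted threshold. Under scaling to the 75th percentile miR-92b (-0.29), miR-279c (-0.037) and miR-971 (-0.0070) turned negative, and miR-305 and miR-306 turned positive (0.016 and 0.038) without normalization. Without dsVg pool 5 the differences were -0.17 for miR-13b, 0.25 for miR-279c, 0.29 for miR-971, 0.27 for miR-3719 and -0.19 for miR-305, without dsGFP pool 3 that of miR-71 was -0.17, without dsVg pool 1 that of miR-92b was 0.099, and without dsGFP pool 4 that of miR-306 was -0.067. With the pool number as a block the adjusted p of miR-3789 was 0.0620 with limma, although the numbers were not treated as pairs. The difference of miR-14, a regulator of ecdysone and insulin signalling in flies, was -1.54 (SE 1.48), the only one above 1 in size, and its levels were 12.09 ± 2.38 in controls and 10.54 ± 3.17 after knockdown. It was -0.91 without dsVg pool 1, -2.53 without dsVg pool 3 and -0.26 without dsVg pools 1 and 5, and it was -0.060 within the arrays whose dim spots lay above the empty spots and -3.03 within the others.

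Over all 84 miRNAs, 45 were higher and 39 lower after knockdown, with a median difference of 0.03. This split follows the scaling: 12 were higher and 72 lower after scaling to the 75th percentile (median -0.31), 59 and 25 after scaling to the median (0.09), and 67 and 17 without normalization (0.15). Either scaling shifts all miRNAs by the same amount from the differences without normalization. All directions given for single miRNAs, above and below, are relative to the quantile-normalized median. The 95% interval of the difference reached 0.41 to either side at the median over miRNAs, or 1.33-fold, and 0.58, or 1.49-fold, for the 33 detected on all arrays. Intervals lay within a 2-fold change either way for 67 miRNAs, 22 of them among those 33, and 17 intervals did not exclude such a change. The intervals do not include the choice of normalization or of background correction. Near background the processing compresses differences, so a narrow interval there does not exclude a 2-fold change in abundance. The interval of miR-375 was -0.64 to -0.12, and plain background subtraction put its difference at -1.63. Under that setting spots below a floor of 1 were raised to 1 before the log2 step. The value of -1.63 therefore need not be the size without compression, and the deposited table gave -0.58. The intervals of miR-184 (-0.07, 95% interval -0.28 to 0.15) and miR-277 (-0.12, 95% interval -0.34 to 0.09) were narrow. Quantile normalization compresses such bright probes, however, and both values left their intervals under scaling to the median (0.28 and 0.22) and without normalization (0.34 and 0.28). Intervals were wide for miR-124 (-0.04 to 1.75), miR-7 (-1.66 to 0.82) and miR-3789 (-1.96 to 0.30).

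**Figure D2:**
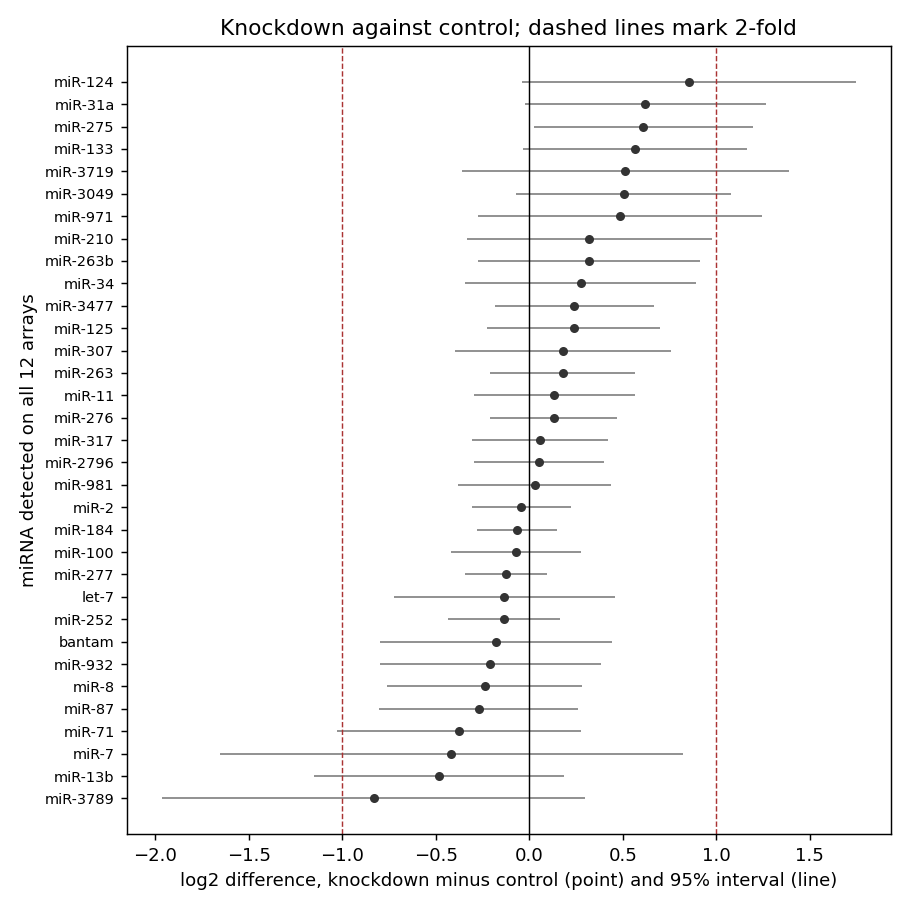
Differences in log2 signal (horizontal axis, knockdown minus control, points) with 95% intervals (lines) for the 33 miRNAs detected on all 12 arrays, 6 pools per group. All intervals but that of miR-275 include 0, and 22 of them lie within the dashed lines at a 2-fold change.

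The lists asked whether miRNAs with shared roles or genes moved together. Their members mostly had small differences, and with 1 pool left out the difference of 33 of the 43 named miRNAs changed by more than 1.5 times or in sign. Without dsVg pool 5, for instance, miR-279 was at -0.080, miR-8 at -0.040, miR-34 at 0.14, miR-3477 at 0.081, miR-263b at 0.17 and miR-263 at 0.032, while miR-9a was at 0.024 without dsVg pool 3 and miR-125 at 0.088 without dsGFP pool 6. Among 17 tested brain and neuronal miRNAs, 8 were higher and 9 lower after knockdown, with miR-124 at 0.85, miR-133 at 0.57, miR-279 at -0.39 and miR-125 at 0.24. The camera p of this list was 0.744 (adjusted p = 0.981). Among 12 miRNAs discussed in earlier honey bee work on nurses and foragers, 7 were higher and 5 lower, with miR-31a at 0.62 and miR-13b at -0.48. The camera p was 0.328 (adjusted p = 0.902). For hormone and insulin signalling 4 were higher and 6 lower, among them miR-14, miR-8 (-0.24) and miR-252 (-0.13), the camera p being 0.539 (adjusted p = 0.981). The difference of miR-252 was positive under median scaling or none. It was -0.33 under scaling to the 75th percentile, -0.35 with cyclic loess and -0.44 in the deposited table. After quantile normalization it was 0 without dsVg pool 3, because the other 11 pools share the highest quantile. For metabolism 2 were higher and 4 lower, among them miR-275 and, with lower signals, miR-305 (positive without normalization) and miR-277, the camera p being 0.288 (adjusted p = 0.902).

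Among miRNAs encoded together in insect genomes, all 3 tested members of the cluster of miR-71, miR-2 and miR-13 had lower signals, with miR-71 at -0.38, miR-13b at -0.48 and miR-2 at -0.04, although miR-2 turned positive with each of the 4 other between-array settings run (75th percentile, median, cyclic loess, none). Single pools carry much of the other 2 as well: miR-13b was at -0.17 without dsVg pool 5 and at -0.028 within the arrays whose dim spots lay above the empty spots, and miR-71 was at -0.17 without dsGFP pool 3. This list had the smallest camera p, 0.0694 (adjusted p = 0.764, and adjusted p = 0.986 with an estimated correlation). The let-7 complex, which answers to ecdysone in flies, was split, with let-7 at -0.13, miR-100 at -0.07 and miR-125 at 0.24, the last turning to -0.09 under scaling to the 75th percentile (camera adjusted p = 0.981). The signs of the other 2 are not firm either: let-7 was at -0.78 within the arrays whose dim spots lay above the empty spots and 0.51 within the others, and with 1 pool left out it ran from -0.29 to 0.0053 and miR-100 from -0.15 to 0.064. The cluster of miR-34 (0.28), miR-277 (-0.12) and miR-317 (0.06), the list of miR-9a (0.18), miR-79 (0.12) and miR-306 (-0.10) and the cluster of miR-12 (-0.28), miR-283 (0.03) and miR-3477 (0.24) each had 2 members higher and 1 lower. Of miR-9a, miR-79 and miR-306, only the last 2 were found as genomic neighbours. Under scaling to the 75th percentile miR-9a, miR-79, miR-283 and miR-3477 turned negative. Without normalization miR-306 and miR-277 turned positive, and miR-277 also did under scaling to the median. These splits also changed with the arrays used: miR-12 was at 0.093 within the arrays whose dim spots lay above the empty spots and -0.66 within the others, miR-277 at -0.31 and 0.057, and miR-317 at -0.17 in the former and -0.044 without dsVg pool 5. Camera's adjusted p was 0.981 for all 3. The difference of miR-34 stayed positive, from 0.0049 to 0.90 over its 35 alternatives. It was 0.90 without normalization, 0.84 under scaling to the median, 0.51 with cyclic loess and 0.50 in the deposited table. The 2 tested members of the cluster of miR-275 and miR-305 lay on opposite sides of 0 (0.61 and -0.29), but miR-305 was at 0.081 within the arrays whose dim spots lay above the empty spots and -0.67 within the others. Those of the family of miR-92 and miR-25, miR-92a (0.33) and miR-92b (0.15), were both higher, and both turned negative (-0.17 and -0.29) under scaling to the 75th percentile. These 2 lists were too short for a test.

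Markers of tissues that could be dissected along with the brain were examined in the same way. The muscle miRNAs lay on opposite sides of 0, with miR-1 at -0.90 and miR-133 at 0.57, and had no list test. The 3 sensory organ and eye miRNAs gave miR-263b at 0.32, miR-263 at 0.18 and miR-7 at -0.42, the first 2 turning negative under scaling to the 75th percentile and miR-263 also under cyclic loess and within the arrays whose dim spots lay above the empty spots (camera adjusted p = 0.981). The difference of miR-7 turned positive with array weights (0.40), without dsVg pool 5 (0.11) and without dsVg pools 1 and 5 (0.29). Of the 6 gut, fat body and epithelial miRNAs, 5 were higher, among them miR-989 and miR-750 (0.11), which both turned negative under scaling to the 75th percentile, and 1, miR-375, had a lower signal. The camera p of that list was 0.283 (adjusted p = 0.902). Adjusted over the list alone, miR-375 reached a limma p of 0.0445, whereas 0 miRNAs passed over all 84 tested, and the other 13 lists held 0 such miRNAs. None of the 11 lists passed camera's adjusted threshold of 0.05, and none did with an estimated correlation (adjusted p = 0.986 for each). The fry test, which asks whether a list moves to one side, gave 0.106 as its smallest p, for the cluster of miR-71, miR-2 and miR-13. Median, mean and camera direction differed in sign for the let-7 complex (-0.07, 0.01, down), the brain list (-0.07, -0.03, up), the cluster of miR-34, miR-277 and miR-317 (0.06, 0.07, down) and the cluster of miR-12, miR-283 and miR-3477 (0.03, -0.0039, down).

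The pools were also compared by how their signals followed the GC content of the miRNA, which affects binding to a probe. The GC trend of a pool is the slope of its deviations from each miRNA's mean over pools, fitted across the 33 miRNAs detected on all arrays. It was -0.11 ± 0.08 per 10 percentage points of GC in controls and 0.11 ± 0.46 after knockdown (log2, SD, n = 6, exact permutation p = 0.355). The 2 group means are equal and opposite by construction, so the control value does not show a trend of the controls' own. The largest trends were 0.92 in dsVg pool 5 and 0.34 in dsVg pool 1, and the lowest was -0.33 in dsVg pool 3, against -0.23 to 0.02 in controls. Several miRNAs named above for higher signals are GC-rich, among them miR-275 (60.9% GC) and miR-124 (56.5%), and miR-1 (36.4%) and miR-13b (34.8%), named for lower signals, are not. Others run against this: miR-3789 (59.1%) was lower, and miR-971 (43.5%) and miR-3719 (45.5%) were higher. Without dsVg pools 1 and 5, 0 miRNAs passed the adjusted threshold, and 10 of the 43 named miRNAs changed sign. Of these, 6 turned negative (miR-279c, miR-3719, miR-317, miR-3477, miR-263b and miR-2796) and 4 positive (miR-100, miR-279, miR-8 and miR-7). A GC slope was also removed from each array, fitted over all 84 tested miRNAs and not over the 33 that define the GC trend. With it removed 0 passed as well, and 7 had an unadjusted limma p under 0.05.

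**Figure D3:**
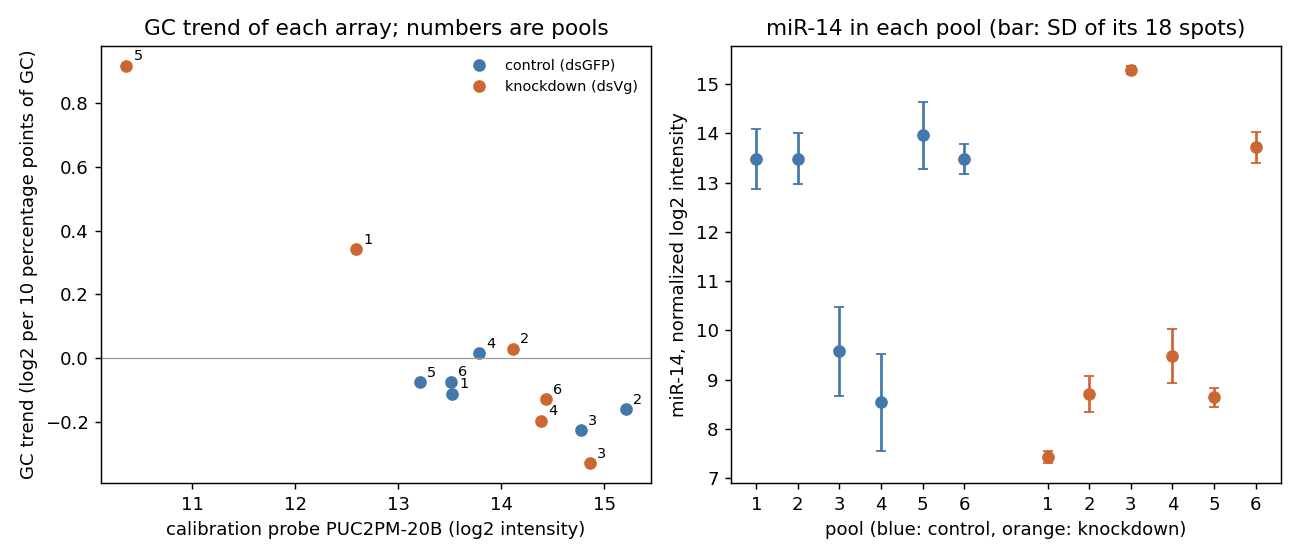
Left, GC trend of each array (log2 per 10 percentage points of GC) against the log2 intensity of the synthetic calibration probe PUC2PM-20B, each point 1 pool with its number. Right, normalized log2 intensity of miR-14 in each pool, with the SD of its 18 spots as a bar, which ran from 7.43 in dsVg pool 1 to 15.28 in dsVg pool 3.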

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

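The splits of the samples and the effect of the GC slope on the spread and on miR-14 were tests set before their results were seen. The tests of the calibration probes, of the number of knockdown trends within the control range, of the distances between pools and of miR-14 in the deposited table were chosen after the result was seen.

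Single pools stood apart from the other 5 of their group in 13 of 98 group tests (the gap to the nearest pool exceeded Dixon's 95% limit), where chance gives about 4.9 if the tests are independent, which they are not. In the knockdown group these were miR-1 in pool 1 (6.63, the others 8.18 to 8.83), miR-13b (10.51), miR-87 (12.86) and miR-2796 (13.96) in pool 5, and miR-252 (14.48) and miR-184 (13.96) in pool 3. The last 2 follow from rank: miR-14 takes the highest quantile (15.28) in dsVg pool 3, where miR-252 has it in the other knockdown pools. In the control group they were miR-275 (10.51) and miR-3049 (8.83) in pool 4, miR-92b in pool 5 (6.53), miR-125 (9.20) and miR-2 (12.86) in pool 6, and miR-7 in pool 3 (13.49), all as normalized log2 intensity. The calibration probe PUC2PM had a log2 intensity of 13.44 in dsGFP pool 2, against 14.96 to 15.36 in the other control pools. Outside the miRNA probes, the mean log2 signal of the 6 probes named for 5S RNA was 11.50 in dsVg pool 3 and 12.04 in dsVg pool 5, above all 6 control pools (9.44 to 10.52). The group means of this measure were 10.03 ± 0.43 and 10.46 ± 1.04 (SD, n = 6, exact permutation p = 0.392).

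The count of miRNAs past the adjusted threshold was 0 in the real split, which every split reaches, so the splits do not bear on it. Of 100 splits of the 12 pools into 6 and 6 (drawn from 462, the real one included), 100 reached at least that count, and the highest other count was 1. For the 3 miRNAs at an unadjusted p under 0.05, 47 of the 100 splits gave as many, and the highest other count was 18. Chance is not excluded for the count of 3.

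The GC trend differed most between the knockdown pools, from -0.33 in pool 3 to 0.92 in pool 5 (log2 per 10 percentage points of GC). Against a uniform effect of the knockdown, 3 of 6 knockdown pools had trends within or below the control range. Differences in hybridization or wash stringency between arrays may account for the trend: it followed the synthetic calibration probe PUC2PM-20B over the 12 arrays with r = -0.933 (permutation p = 0.000190, adjusted p = 0.000823 over 13 calibration probes; rho = -0.825, permutation p = 0.00158). The r was -0.63 without dsVg pools 1 and 5, -0.67 within controls, -0.99 within the knockdown group, and -0.91 and -0.94 within the 2 kinds of array, and 3 of the 13 probes passed adjustment by r, all of the PUC2PM-20B kind, against 7 by rho. Not all probes followed the trend: r was positive for PUC2PM (0.08), a-PUC2PM (0.26), Ctr06-3P (0.20) and Ctr09-3P (0.20), and negative for the others. The 13 were those of 43 calibration probes that were detected on all arrays. An effect of the knockdown that differs between pools stays open and was not tested.

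The knockdown pools lay farther from their group centre than the control pools, at a mean distance of 0.55 against 0.36 (root mean square of the log2 deviations over 84 miRNAs), a ratio of 1.53. Chance is not excluded for this ratio (exact permutation p = 0.104). With the GC slope over all 84 miRNAs removed from each array the ratio was 1.46 (exact permutation p = 0.117). That slope is not the GC trend of the 33 miRNAs detected on all arrays, so part of the trend may remain. A linear slope also need not remove all of a hybridization effect. How much of the spread the GC trend explains cannot be told from these pools. Without miR-14 the ratio was 1.66, and with 1 pool left out it ran from 1.32 (without dsVg pool 5) to 1.80 (without dsGFP pool 3), with an exact permutation p of 0.0411 without dsVg pool 4, 0.0455 without dsVg pool 2 and 0.0779 to 0.314 without any of the others. A more variable response of the knockdown bees stays open as a hypothesis and was not tested.

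The signal of miR-14 had an SD of 2.79 over the 12 pools, where the next largest among the 84 miRNAs was 1.17, and it spanned 7.86 log2 units (8.04 without normalization), with its low end near background. It lay between 13.49 and 15.28 in dsGFP pools 1, 2, 5 and 6 and dsVg pools 3 and 6, and between 7.43 and 9.58 in the other 6 pools. Against an origin in the processing used here, the deposited table spans 7.14 log2 units for this miRNA. Against the GC trend as the whole cause, its SD stays at 2.66 with the GC slope over the 84 miRNAs removed, although that slope need not hold all of the trend. Its 18 spots were also uneven, with an SD of 0.44 at the median and 0.98 at most, on 7 arrays above that of each of the 33 miRNAs detected on all arrays (miR-14 itself was detected on 11). A probe fault on some arrays and a real difference between pools of bees both stay open, and no biological explanation was tested beyond the group difference in the report.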

How the results depend on the processing

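Alternatives chosen after seeing the data were the removal of the GC slope, with and without the replicate block, the calibration probe as a covariate, the kind of array as a block, each kind of array alone, and the knockdown group without pools 1 and 5. The planned slide or scan block was not run, because the files give no slide or scan. The cause was not tested for any change below.

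The count of miRNAs past the adjusted threshold was 0 under 35 of 36 alternatives and 1 with array weights, where miR-375 had an adjusted limma p of 0.0385 (0.0385 to 0.984 over its 34 alternatives). All 31 alternatives of the list tests gave 0 lists. The count at an unadjusted p under 0.05, 3 in the report, was 1 with plain background subtraction or median scaling, 7 with cyclic loess, 6 without a filter or from the deposited table, 12 with array weights, 7 with the GC slope removed, 6 with the calibration probe, and 1 and 5 within the 2 kinds of array. It ran from 1 to 13 with 1 pool left out. Pool numbers 1 to 6 recur in both groups. Same-numbered pools correlated at -0.27 to 0.53, 2 of 6 above 0.1, and 0 of 6 knockdown pools correlated best with their own number. The numbers were not treated as pairs, but these correlations do not exclude pairing. They weigh each miRNA by its spread, so miR-14 counts most (SD 2.79 over the pools, the next largest 1.17). With the replicate block the count past the adjusted threshold was 0 and the unadjusted count 3 (6 with the GC slope also removed), and it changed no call at the threshold of 0.05. It did lower the adjusted limma p of miR-3789 to 0.0620 (0.0584 with the GC slope also removed), so that 1 miRNA lay under 0.1 with either block, against 0 in the report. Its unadjusted limma p with the block was 0.000738, the smallest of the named miRNAs, and its difference was below 0 in all 6 same-numbered pairs (-1.34 to -0.29). With dsGFP pool 3 left out, the adjusted limma p of miR-375 was 0.0564, also under 0.1. With any other pool left out that of miR-375 was 0.2215 to 0.927. The difference in detected miRNAs was 8.33 with 3 background SDs and ran from -27.3 to 2.53 with 1 pool left out. That in median signal was -0.034 within the arrays whose dim spots were level with the empty spots and ran from -0.047 to 0.13 with 1 pool left out. Where dim miRNAs lie at the level of the empty spots, signal over background limits what any setting can show.

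Of 1489 single values of the 43 named miRNAs, 1413 kept their direction and their side of the threshold, and the direction of 13 miRNAs never turned. Part of this was fixed in advance. The variance models, the permutation test, the blocks for pool number and kind of array, and the filters on dim probes leave the difference itself unchanged. Fits with 1 pool left out share most of their data. The share that kept its direction is therefore no measure of stability. Among the 1413 are 4 values that are 0 apart from rounding error and have no direction: miR-252 without dsVg pool 3, miR-252 and miR-184 within the arrays whose dim spots were level with the empty spots, and miR-87 without dsVg pools 1 and 5. Turned values (log2) were the following. Those under scaling to the 75th percentile or to the median come from a shift that all miRNAs share. Scaling to the 75th percentile gave miR-989 -0.030, miR-92a -0.17, miR-3049 -0.0061, miR-92b -0.29, miR-279c -0.037, miR-971 -0.0070, miR-125 -0.087, miR-2 0.017, miR-9a -0.027, miR-79 -0.12, miR-3477 -0.22, miR-283 -0.26, miR-263b -0.038, miR-263 -0.31 and miR-750 -0.30. Scaling to the median gave miR-252 0.073, miR-277 0.22, miR-2 0.42, miR-184 0.28 and miR-87 0.054. No normalization gave miR-305 0.016, miR-306 0.038, miR-252 0.13, miR-277 0.28, miR-2 0.48, miR-184 0.34 and miR-87 0.11. Cyclic loess gave miR-2 0.089 and miR-263 -0.100, the median of spots miR-2 0.010 and miR-2796 -0.056, the deposited table miR-2 0.13, and plain subtraction and no background correction miR-283 -0.098 and -0.0048. Array weights gave miR-100 0.015, miR-8 0.11, miR-2 0.047, miR-3477 -0.011 and miR-7 0.40. The GC slope removed gave miR-92b -0.010 and miR-2796 -0.079, the same with the replicate block, and the calibration probe gave miR-317 -0.0097. Arrays with dim spots above the empty spots gave miR-305 0.081, miR-12 0.093, miR-317 -0.17, miR-263 -0.018 and miR-2796 -0.065, and the others let-7 0.51, miR-100 0.12, miR-277 0.057 and miR-283 -0.011. Without dsVg pools 1 and 5 the values were miR-279c -0.030, miR-3719 -0.018, miR-100 0.0025, miR-279 0.10, miR-8 0.089, miR-317 -0.034, miR-3477 -0.023, miR-263b -0.064, miR-7 0.29 and miR-2796 -0.042. With 1 pool left out, let-7 ran from -0.29 to 0.0053, miR-100 from -0.15 to 0.064, miR-184 from -0.094 to 0.010, miR-2 from -0.097 to 0.033, miR-2796 from -0.031 to 0.16, miR-283 from -0.010 to 0.089, miR-317 from -0.044 to 0.18 and miR-7 from -0.64 to 0.11.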

Other observations

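The test of genomic neighbours was set before its result was seen.

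The steadiest signals over the 12 pools among the 33 miRNAs detected on all arrays were those of miR-184 (SD 0.15 on the log2 scale), miR-277 (0.16) and miR-2 (0.19), all bright probes whose spread quantile normalization compresses. The most variable were miR-7 (SD 1.04), which acts in sensory organ and photoreceptor development in flies, miR-3789 (1.03) and miR-124 (0.86). The SD of miR-7 was 0.55 among controls and 1.41 after knockdown, that of miR-124 was 0.33 and 1.04, and that of bantam, a growth-promoting miRNA in flies, was 0.10 and 0.74, whereas that of miR-3789 was 1.04 and 0.91. Single pools carry much of this: without dsVg pool 5 the SD after knockdown was 0.57 for miR-7, 0.80 for miR-124 and 0.17 for bantam. miR-7, miR-124 and bantam were chosen after their values were seen, and bantam lies outside the naming rule. Over the 84 miRNAs the median SD was 0.23 in controls and 0.37 after knockdown, or 0.28 without dsVg pool 5.

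Another miRNA chosen after its values were seen, miR-29b, had a signal of 11.17 ± 0.30 in controls and 10.48 ± 1.63 after knockdown (SD, n = 6), a difference of -0.68 (SE 0.62, exact permutation p = 0.383, adjusted p = 0.772 with limma). It rests on dsVg pools 1 and 5 (8.27 and 8.71, the other knockdown pools 11.08 to 12.41): the difference was -0.24 without pool 1, -0.33 without pool 5 and 0.31 without both.

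A hypothesis was that miRNAs encoded close together would vary together between pools, as shared transcription predicts. Over 17 pairs of tested miRNAs within 10 kb of each other, the mean correlation over the 12 arrays, with group means and GC slopes removed, was 0.0810, at the 77.0th percentile of 10000 random sets of 17 pairs. The mean lay neither above nearly all random sets nor below their median, so the test decides nothing about shared transcription. Pairs went both ways, and the removal of the GC slope changed them strongly: miR-283 and miR-3477 stood at 0.88 with it and -0.38 without, and miR-279 and miR-996 at -0.61 and 0.51. Among the pairs positive both ways were miR-193 and miR-2788 (0.62 and 0.66) and let-7 and miR-100 (0.46 and 0.56). Among those negative both ways were miR-275 and miR-305 (-0.48 and -0.71) and miR-1175 and miR-750 (-0.22 and -0.18). Several of these miRNAs lie near background: miR-193, miR-750 and miR-996 were detected on 6 of the 12 arrays, and miR-1175 and miR-283 on 7. Noise near background therefore enters their correlations. Whether neighbours lie on the same strand was not known.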
